A study of Mus musculus with 18 samples.

How the data were processed

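RNA sequencing libraries were made from CD4 T cells isolated by negative enrichment from the spleens of female NZB/W F1 mice, a hybrid that develops a lupus-like disease. Per the labels' protocols, the mice were 21 to 27 weeks old with 30 to 100 mg/dL of proteinuria, and cells were plated at 250000 per well with IL-2 at 10 U/mL. Each well received an anti-Ox40 antibody of the IgG1 class or an isotype control IgG1 (control Ig) at 25 µg/mL, together with beads carrying anti-CD3 and anti-CD28 antibodies at 0 (no beads), 0.1 (low beads) or 1 (high beads) per cell. RNA was collected after 48 hours, and libraries were built from 100 to 500 ng of RNA with 10 cycles of PCR. The 18 libraries form 6 groups of 3. The labels do not say whether replicates came from separate mice, from separate cultures or from the same pool of cells, and give no batch and no number shared between groups. By the labels, replicate numbers are therefore only names in accession order, and the main model does not pair libraries by them. Each of the 18 libraries nevertheless correlated best with 1 of its own number in another group, in its deviation from the group mean. A fit with the number as a block is therefore given among the alternatives.

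The authors deposited 1 table of nRPKM values for these libraries, which are RPKM values (read numbers divided by gene length and by library size) with a further normalization between libraries, as the name of the unit states. Reads were aligned with GSNAP to GRCm38, per the submitters' processing notes, which give no version. The annotation, the counting of reads and the way libraries were scaled are not given in the sources used here. The table holds 36528 entries, of which 6 have no symbol, 27 have a symbol turned into a date and 6 share a symbol with another entry. Sums of the deposited RPKM values ranged from 273498 to 348466 per library. No 2 libraries were identical.

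Read numbers are not given in the table, and a depth was worked out from the values. In each library, the values of microRNA genes with a known length, taken as 1 to 5 reads, fell on whole multiples of a single unit for 100% of those values, within 0.1 read. On the authors' scale, which includes their normalization factor, an nRPKM of 1 over 1 kb then stands for between 26.4 and 46.0 reads, depending on the library. These figures give counting error only.

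Genes were tested when they had an nRPKM of at least 1 in at least 3 of the 18 libraries, which left 13075 genes. Values were taken to log2(nRPKM + 1), so that fold changes of genes with low values are understated. A single model with a mean for each of the 6 groups was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend, 12 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. The contrasts were anti-Ox40 against control Ig at each of the 3 bead doses, the 3 pairs of bead doses within control Ig, and the 3 differences of the antibody effect between doses. All p-values measure only the spread between these libraries. This test, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined.

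Coordinates are 1-based positions on GRCm38 from a RefSeq annotation of that build, which matched 12292 of the 13075 tested genes (94%). Genes without a match, among them several LOC symbols, are named by the symbol in the deposited table alone. Without the reads, it was not possible to test whether a gene shares reads with copies of it elsewhere, such as Gapdh, or Tpi1 and LOC102642803. For microRNA and small nucleolar RNA genes inside another gene, reads of the host transcript cannot be separated from those of the small RNA.

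Named genes were chosen by rule. Tnfrsf4, which encodes Ox40, its ligand gene Tnfsf4, Il2ra and Cd69 were reported in every comparison. For the 3 antibody comparisons and for high against no beads in control Ig, the 12 called genes with the largest increase and the 12 with the largest decrease were taken. For the other comparisons 5 of each were taken. In all comparisons of 2 groups the libraries of the groups also had to be fully separated, which chance gives for 10% of genes at 3 against 3. Symbols that start with Gm and a digit or end in Rik or in -ps with or without a digit, symbols turned into dates and entries without a symbol were passed over. LOC symbols were not. For each gene list up to 4 members with the smallest adjusted p were added. The results of some genes that this rule names are not reported here.

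In all, 34 gene lists were used. The 24 theme lists cover the TNF receptor superfamily and its ligands, NF-kB pathway and feedback genes, survival and pro-apoptotic members of the BCL2 family, T cell activation, naive and quiescence genes, Th1, Th2, Th17, Tfh and Treg genes, T cell cytokines, checkpoint receptors, the IL-2 and STAT5 response, the type I interferon response, DNA replication, mitosis, glycolysis, cholesterol synthesis, the amino acid response with one-carbon metabolism, ribosome biogenesis, oxidative phosphorylation, the p53 response and cytotoxic effector genes. The 10 marker lists cover CD4 T cell identity, CD8 T cells, B cells, plasma cells, myeloid cells, dendritic cells, NK cells, neutrophils, erythroid cells and platelets. The CD8 and erythroid lists had 1 tested member each and were not tested as lists. Lists were tested with camera from limma at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists within a contrast. Unlike camera, fry asks only whether the members changed, without comparing them with other genes. Its adjusted p-values for a shared direction are given for the lists called in the antibody comparisons. The preset correlation was the planned test, and the result with the estimated correlation is printed beside it. Counts of called members are given over all genes tested and adjusted over the list alone.

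The fit was tested on simulated data drawn from the fitted means and spreads of the 13075 genes, with 200 genes changed in each of 10 draws. For anti-Ox40 with no beads it found 81.9% of changes of 0.5 and 95.3% of changes of 1 on the log2 scale, with 4.7% false calls. For low beads the shares were 82.7%, 95.0% and 4.0%, and for high beads 81.3%, 96.1% and 4.8%. Simulated genes varied independently of each other, which real genes do not, and no simulated library departed as a whole from its group. The simulated sizes also exceeded the median absolute change of real called genes, 0.26 at low and 0.28 at high beads. These shares therefore say nothing about changes that small.

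The first set of alternative settings held pseudocounts of 0.1 and 0.5, no filter, a filter at an nRPKM of 5, quantile normalization, median-ratio rescaling, a fit to only the groups compared, a fit without the trend, robust moderation, an estimated inter-gene correlation for the lists, and leaving out each library in turn. After the data were seen, 6 more were added. These were leaving out the 6 libraries with the highest B cell markers of their group, leaving out the 6 with the lowest as a reference, using a B cell marker score, a nuclear RNA score or a lung transcript score as a covariate, and using the replicate number as a block. Figures and the depth estimate used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.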

Results

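RNA levels were compared between 18 libraries of splenic CD4 T cells cultured from the lupus-prone NZB/W F1 hybrid, 3 in each of 6 groups. The series set out to describe the expression signature of Ox40 signalling combined with T cell receptor signalling. As a measure of depth, an nRPKM of 1 over 1 kb stood for 35.3 ± 1.05 reads (SD, n = 3) in control Ig and 30.9 ± 4.26 in anti-Ox40 cultures without beads. It stood for 38.5 ± 6.51 and 36.2 ± 6.44 reads at low beads, and for 34.1 ± 0.55 and 38.5 ± 5.72 at high beads. Between 11763 and 12261 genes per library had an nRPKM of at least 1. Across genes, libraries of the same group correlated at 0.989 to 0.995 (Pearson). The first principal component held 82.2% of the variance and the next held 8.8%. Values below are mean nRPKM ± SD of 3 libraries, fold changes are differences of log2(nRPKM + 1) with their standard errors (SE), and adjusted p-values are from limma.

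The bead comparisons within control Ig show the response to stimulation of CD3 and CD28 on which the antibody acted. At high beads Il2ra, the high-affinity IL-2 receptor chain, rose from 79.4 ± 5.51 to 650 ± 49.2 (log2 fold change 3.02, SE 0.08, adjusted p = 4.72e-15). Tnfrsf4 (chromosome 4, 156013595 to 156016613) rose from 30.4 ± 1.80 to 114 ± 12.4 (1.87, SE 0.08, adjusted p = 1.47e-12), and its ligand Tnfsf4 rose from 0.83 ± 0.16 to 2.68 ± 0.33. Cd69, an early activation marker, rose from 6.99 ± 0.23 to 12.1 ± 0.72. All 25 tested mitosis genes and all 27 DNA replication genes rose, as did all 19 glycolysis genes, with median log2 changes of 4.15, 2.98 and 2.42.

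In that comparison of high with no beads, 10767 of 13075 genes were called, 5680 higher and 5087 lower, with a median change over all genes of 0.04. The largest increases included Scd2, a fatty acid desaturase (5.78), with the microRNA gene Mir5114 inside it (6.30), the steroid-synthesis enzyme Cyp11a1 (5.79) and the cytokine gene Il24 (5.70). Tnfrsf8, which encodes CD30, rose by 5.62. Others were the lactate transporter Slc16a3 (5.43), Tpi1 (5.28) and LOC102642803, which had no match in the annotation and whose level followed Tpi1 (5.28), the transcription factor Irf4 (5.20), Tgm2 (5.10) and Top2a (5.05). Scgb1a1, a secretory protein of lung airway cells, was listed at 0 in the libraries without beads and at 46.2 ± 33.6 with high beads. The largest decreases included Lyz2, the lysozyme of myeloid cells, from 213 ± 16.3 to 3.97 ± 2.56 (-5.55), Clec4n (-4.58), Cpne7 (-4.46) with Mir7080 inside it (-3.72), and the small nucleolar RNA gene Snord35b (-4.21). They also included Pydc3 (-3.97), Peg13 (-3.71), Lpar6 (-3.51), Ifi203 (-3.50), Il18r1 (-3.50), Mpeg1 (-3.44) and Igj (-3.42). Naive and quiescence genes fell (17 of 21 lower, 2 higher), and T cell activation genes (16 of 20 higher, 1 lower) and Th2 genes (12 of 14 higher) rose. The list calls had adjusted p-values of 1.49e-05, 0.000123 and 0.00068 with camera at its preset correlation, and adjusted p = 0.227 for each with an estimated correlation. The glycolysis, mitosis and DNA replication calls (2.91e-09, 2.37e-12 and 2.37e-12) also had adjusted p = 0.227 with an estimated correlation.

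Genes of dividing cells were among the largest increases at low beads. Top2a rose from 7.20 ± 0.51 to 173 ± 22.7 (log2 4.40, SE 0.10, adjusted p = 8.45e-15), and Ube2c (4.12), Rrm2 (4.03), Igfbp4 (4.01) and Ccnb2 (4.01) followed. Il2ra rose by 1.58, Tnfrsf4 by 0.46 and Tnfsf4 by 0.32, while Cd69 differed by 0.08 (adjusted p = 0.431). Low against no beads called 8152 genes, 4260 higher and 3892 lower, with Lyz2 (-3.82), Clec4n (-3.59), Pla2g7 (-3.01), Gpnmb (-2.99) and Mpeg1 (-2.64) the most reduced. From low to high beads 9483 genes were called, 5231 higher and 4252 lower. With a nuclear RNA score as a covariate the count was 5728. This score was 6.93 to 7.88 in control Ig at low beads and 6.36 to 6.62 at high beads. Tgm2 (4.91), Il24 (4.51), the prolyl hydroxylase Egln3 (3.84) and the metallothioneins Mt2 (3.76) and Mt1 (3.76) rose most. Snord35b (-2.96), Pydc3 (-2.86), Ifi203 (-2.79), Drc1 (-2.74) and Scg5 (-2.69) fell most. Tnfrsf4 (1.41), Il2ra (1.44), Tnfsf4 (0.69) and Cd69 (0.63) all rose between these doses.

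Markers of several other cell types moved with the beads. All 15 myeloid markers were lower at high than at no beads (median -1.85, camera adjusted p = 4.44e-06, adjusted p = 0.227 with an estimated correlation). In control Ig cultures, Csf1r went from 6.61 ± 0.36 without beads to 0.04 ± 0.02 with high beads, the NK cell marker Klrd1 from 30.1 ± 2.69 to 2.94 ± 0.75 and the platelet marker Pf4 from 39.2 ± 5.54 to 6.76 ± 1.01. Neutrophil markers fell (7 of 8 lower, 1 higher, adjusted p = 0.0293, adjusted p = 0.377 with an estimated correlation), as did platelet markers (7 of 8 lower, 1 higher, 0.0193 and adjusted p = 0.362 with an estimated correlation). NK cell (6 of 8 lower, 1 higher, camera 0.0845) and dendritic cell markers (5 of 8 lower, 1 higher, 0.104) were not called as lists. Neither were B cell (2 of 12 lower, 0.359) and plasma cell markers (4 of 8 higher, 3 lower, 0.705). Cd4 itself was listed at 308 ± 16.6 without beads and 193 ± 3.07 with high beads, and group means of Cd8a lay between 0.119 and 0.186.

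The comparisons of anti-Ox40 with control Ig show what the antibody added at each level of stimulation. Without beads, anti-Ox40 raised few genes, Scin and Tnfrsf8 among them. Scin, an actin-severing protein, rose from 0.97 ± 0.40 to 3.28 ± 0.37 (chromosome 12, 40059769 to 40134228; log2 1.14, SE 0.15, adjusted p = 0.0125), and Tnfrsf8 rose from 0.93 ± 0.06 to 2.36 ± 0.16 (0.80, SE 0.14, adjusted p = 0.0412). The DNA-methylation cofactor Uhrf1 (0.67), the topoisomerase Top2a (0.66), from 7.20 ± 0.51 to 12 ± 1.55, the proliferation marker Mki67 (0.58), and the nucleotide-synthesis enzyme Rrm2 (0.57) rose as well. So did Esco2 (0.55), the spindle genes Tpx2 (0.51), Kif11 (0.47), Spdl1 (0.45) and Kif15 (0.44), and the separase gene Espl1 (0.44).

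In total 18 genes were called without beads, all higher, against 519 at an unadjusted p under 0.05. Among mitosis genes 4 of 25 rose, and 21 of 25 when adjusted over the list alone. The camera test of this list gave adjusted p = 3.09e-48, and adjusted p = 0.056 with an estimated correlation. Among DNA replication genes 3 of 27 rose (8 adjusted over the list alone; 1.27e-21, and adjusted p = 0.213 with an estimated correlation). NF-kB genes (0 of 23 called, also adjusted over the list alone; median 0.05; camera 0.00286, adjusted p = 0.494 with an estimated correlation) were called as a list only. So were cholesterol synthesis (0 of 21; median 0.05; 0.0237, adjusted p = 0.94 with an estimated correlation) and CD4 T cell identity (0 of 16; median -0.06; 0.00568, adjusted p = 0.784 with an estimated correlation). With fry, adjusted p was 0.0416 for mitosis and 0.222 for DNA replication. It was 0.784 for NF-kB genes and for CD4 T cell identity, and 0.992 for cholesterol synthesis. Tnfrsf4 (0.05), Tnfsf4 (0.11), Il2ra (0.15) and Cd69 (0.09) were not called (adjusted p = 1 for each). The 18 calls depended on single libraries and on the settings. There were 0 without control Ig replicate 3 or anti-Ox40 replicate 3 (no beads), 2 without control Ig replicate 1 or anti-Ox40 replicate 2, 7 without control Ig replicate 2 and 30 without anti-Ox40 replicate 1. There were 86 and 32 with pseudocounts of 0.1 and 0.5, 42 with a nuclear RNA score as a covariate, 10 with no trend, 9 with no filter and 3 with a fit to only the groups compared. With the replicate number as a block there were 59.

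At low beads, Il9, Il21, Slc16a3 and Batf3 were among the genes raised by anti-Ox40. The cytokine genes Il9 (chromosome 13, 56479277 to 56482257) and Il21 (chromosome 3, 37222759 to 37232636) rose from 3.17 ± 1.95 to 22.0 ± 9.54 (log2 2.48, SE 0.41, adjusted p = 0.00433) and from 1.52 ± 0.60 to 4.96 ± 1.25 (1.25, SE 0.18, adjusted p = 0.00122). Slc16a3 (chromosome 11, 120948484 to 120959000) rose from 12.7 ± 1.10 to 28.4 ± 1.63 (1.11, SE 0.06, adjusted p = 6.65e-08), and Batf3, an AP-1 family transcription factor (chromosome 1, 191098414 to 191108943), from 1.27 ± 0.14 to 4.38 ± 0.57 (1.24, SE 0.14, adjusted p = 0.000169). Mgarp, which encodes a mitochondrial protein (1.18, adjusted p = 1.19e-06), the retinol transporter Stra6 (1.58) and the Th2 cytokine gene Il13 (1.08) also rose.

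Glycolysis was the list with the largest share of called members at low beads, with 14 of 19 higher and 0 lower (17 adjusted over the list alone), including Tpi1 (0.98), hexokinase Hk2 (0.98) and phosphofructokinase Pfkl (0.66). Its camera adjusted p was 5.38e-19, and adjusted p = 0.0701 with an estimated correlation. Of 19 tested cytokine genes 9 rose (10 adjusted over the list alone; 2.87e-06, and adjusted p = 0.0701 with an estimated correlation), among them Lif (0.53) and Il4 (0.68). Th2 genes rose in 5 of 14 cases (6 adjusted over the list alone), with Il24 (1.08) and the chemokine receptor Ccr4 (0.35) among them, and T cell activation genes in 7 of 20 (7 adjusted over the list alone), with Batf (0.52) and Irf4 (0.66). Their camera adjusted p-values were 0.0026 and 0.00337, and adjusted p = 0.364 and 0.408 with an estimated correlation. In the IL-2 and STAT5 list 3 of 17 rose (4 adjusted over the list alone; 0.0158, and adjusted p = 0.474 with an estimated correlation), with Lta (0.57) beside Lif and Il2ra. With fry, adjusted p was 3.62e-06 for glycolysis, 0.000146 for cytokines and 0.0129 for Th2 and for T cell activation genes. It was 0.0422 for the IL-2 and STAT5 list.

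Biosynthetic and cell cycle lists were also called at low beads with camera at its preset correlation, and none of them with an estimated correlation. The amino acid list had 14 of 21 higher (16 adjusted over the list alone), with asparagine synthetase Asns (0.60), Mthfd1l (0.47), Psat1 (0.37) and the transporter Slc7a5 (0.38). DNA replication had 13 of 27 higher (23 adjusted over the list alone), with Rrm1 (0.30) and Cdc6 (0.30), and cholesterol synthesis 8 of 21 (11 adjusted over the list alone), with Cyp51 (0.39) and Mvd (0.25). The 3 camera calls, at 9.46e-11, 3.14e-11 and 2.82e-07, each had adjusted p = 0.364 with an estimated correlation. Oxidative phosphorylation (6 of 24 higher, 10 adjusted over the list alone; 1.62e-07, adjusted p = 0.474 with an estimated correlation) included Atp5b (0.28), and ribosome biogenesis (4 of 25, 6 adjusted over the list alone; 4.26e-06, adjusted p = 0.501 with an estimated correlation) included the nucleolin gene Ncl (0.24). Mitosis genes were called as a list with 0 of 25 members called, also adjusted over the list alone (median 0.21; 3.76e-05, adjusted p = 0.585 with an estimated correlation). The p53 list had 4 of 15 higher and 1 lower (6 and 2 adjusted over the list alone; 0.00995, adjusted p = 0.566 with an estimated correlation), with the cell cycle inhibitor Cdkn1a (0.83) and Phlda3 (0.63) higher and Trp53inp1 (-0.31) lower. With fry, adjusted p was 0.00341 for amino acid genes, 0.0113 for DNA replication and for cholesterol synthesis, and 0.0334 for oxidative phosphorylation. It was 0.0578 for ribosome biogenesis and for the p53 list, and 0.115 for mitosis.

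Naive and quiescence genes fell at low beads in 5 of 21 cases (8 adjusted over the list alone), among them Il6ra (-0.25), Foxp1 (-0.26), Btg1 (-0.20) and Dgka (-0.30), with camera adjusted p = 3.77e-05, and adjusted p = 0.364 with an estimated correlation. Their fry adjusted p was 0.0279. Survival BCL2 genes, not called with camera (0.339), had fry adjusted p = 0.0422. In the NF-kB list, which was not called (0.432), Nfkb2 (0.64) and the inhibitor Nfkbia (0.54) rose, and Rel (-0.27) and Nfkbiz (-0.30) fell, among 3 higher and 2 lower. Il2ra rose from 240 ± 15.7 to 293 ± 15.8 (0.29, adjusted p = 0.0287) and Cd69 from 7.47 ± 0.60 to 9.84 ± 0.50 (0.36, adjusted p = 0.0251), while Tnfrsf4 (0.18, adjusted p = 0.135) and Tnfsf4 (0.27, adjusted p = 0.126) were not called. Tnfrsf4 was called here in the alternative fit with the replicate number as a block. The largest decreases included small RNA genes and LOC gene models, among them Snora2b inside Kansl2 (-0.75), LOC102635015 overlapping Slc38a1 (-0.69), LOC102641431 (-0.66), Mir3960 (-0.65), LOC102640104 (-0.62) and LOC102641358 (-0.60). The others were Mir8107 inside Nbeal2 (-0.60), LOC102635614 (-0.59), LOC102638917 (-0.58), LOC102640062, a pseudogene overlapping Ifi47 (-0.57), and Mir7029 inside Gcn1 (-0.52), with the transcription factor gene Tbx6 (-0.48).

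In total 1254 genes were called at low beads, 804 higher and 450 lower. This number depended on control Ig low-bead libraries, being 3522 without replicate 2, 131 without replicate 1 and 137 without replicate 3. It was 554, 311 and 318 without anti-Ox40 low-bead replicates 1, 2 and 3. It was 557 with no filter, 45 with a fit to only the groups compared, 222 with a nuclear RNA score and 123 with a lung transcript score as a covariate. At low beads the lung score itself separated the antibody groups, at 0.150 to 0.922 in control Ig and 1.025 to 2.245 with anti-Ox40. This covariate therefore cannot tell lung RNA from the antibody effect. The nuclear RNA Malat1 was at 173 in control Ig replicate 2 against 453 and 435 in replicates 1 and 3, and at 213 to 254 in the anti-Ox40 libraries at low beads. Of 77 named genes called at low beads, 18 stayed called whichever library was left out. Of these, 10 also stayed called under all other settings fixed before the data were examined, namely Batf3, Slc16a3, Mgarp, Tpi1, Hk2, Pfkl, Asns, Nfkb2, Cdkn1a and Mthfd1l. The others, with Il9, Il21, Stra6 and Irf4 among them, lost their call in the fit to only the groups compared.

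Transcripts of lung epithelium were among the largest increases at low beads. Scgb1a1 was at 11.6 ± 10.0 in control Ig and 71.8 ± 66.1 in anti-Ox40 cultures (log2 3.01, SE 0.87, adjusted p = 0.0419), and the surfactant genes Sftpc (2.55) and Sftpb (1.59) and the enzymes Cbr2 (1.48) and Cyp2f2 (1.14) were called with it. Scgb1a1 was at 0 in 7 libraries, including all 6 without beads and 1 control Ig library at low beads, and between 16.4 and 148 in the other 11, in both antibody groups. B cell markers also differed between single libraries, and Ms4a1 (CD20) was at 11.9 in control Ig and 10.6 in anti-Ox40 low-bead replicate 3. It was at 0.305 to 0.479 in the other libraries at low beads. Without the 6 libraries with the highest B cell markers, 1 per group, the calls were 0 without beads, 24 at low beads and 1387 at high beads. Without the 6 with the lowest they were 2, 1923 and 2100, each with 2 libraries per group. At low beads the lowest set held control Ig replicate 2, whose removal alone gave 3522 calls. The highest set held control Ig replicate 3, whose removal alone gave 137. The low-bead counts therefore do not isolate an effect of B cells.

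**Figure D1:**
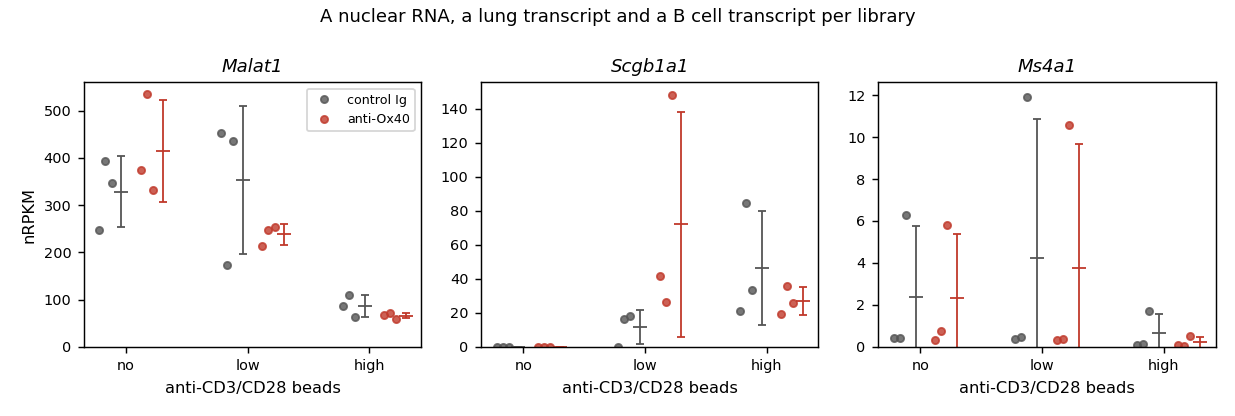
nRPKM (vertical axes, linear) of the nuclear RNA Malat1, the lung transcript Scgb1a1 and the B cell transcript Ms4a1 at no, low and high beads (horizontal axes), with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3) that end at 0 where they would go below it. Control Ig low-bead replicate 2 has less Malat1 (173) than the other libraries without or with low beads, Scgb1a1 is at 0 without beads, and 1 library per group holds most Ms4a1.

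At high beads, Batf3, Il9 and Il21 were among the genes raised by anti-Ox40 and Klf2 among those lowered. Batf3 rose from 7.22 ± 0.75 to 34.6 ± 3.65 (log2 2.12, SE 0.14, adjusted p = 8.8e-07), Il9 from 11.3 ± 4.70 to 87.8 ± 43.5 (2.79, SE 0.41, adjusted p = 0.000253) and Il21 from 20.3 ± 5.02 to 70.7 ± 3.64 (1.78, SE 0.18, adjusted p = 1.63e-05). Klf2, a transcription factor of quiescent T cells (chromosome 8, 72319062 to 72321654), fell from 78.8 ± 14.3 to 36.1 ± 7.28 (-1.11, SE 0.13, adjusted p = 5.83e-05). Cd69 rose from 12.1 ± 0.72 to 23.2 ± 3.69 (0.88, adjusted p = 1.63e-05), Il2ra from 650 ± 49.2 to 856 ± 44.4 (0.40, adjusted p = 0.00129) and Tnfsf4 from 2.68 ± 0.33 to 4.13 ± 0.73 (0.47, adjusted p = 0.00577), while Tnfrsf4 itself was at 114 ± 12.4 and 120 ± 5.39 (0.08, adjusted p = 0.505).

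**Figure D2:**
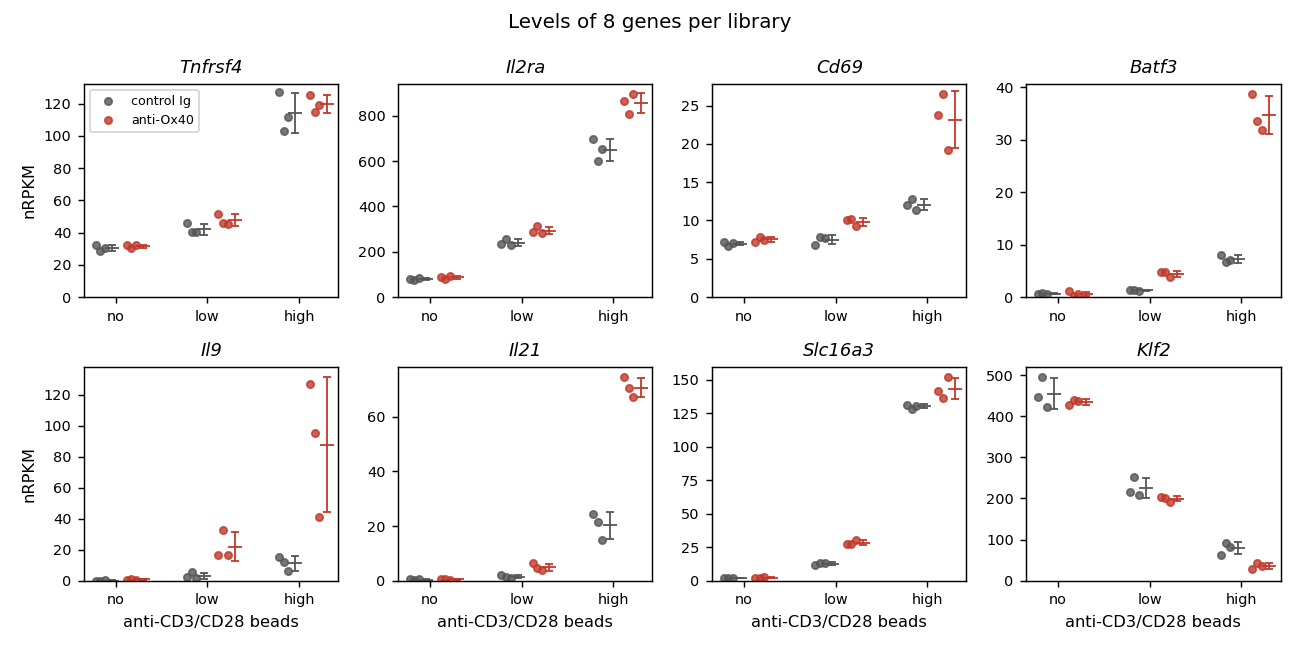
nRPKM (vertical axes, linear) of Tnfrsf4, Il2ra, Cd69, Batf3, Il9, Il21, Slc16a3 and Klf2 at no, low and high beads (horizontal axes), with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3). Batf3 and Il21 separate by antibody at low and at high beads, Slc16a3 is at 12.7 and 28.4 on average at low beads, and Klf2 is at 78.8 and 36.1 at high beads.

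The other large increases at high beads were Stra6 (1.72), the lysophospholipase Enpp2 (1.72), the BCL2-family gene Bcl2l14 (1.68, adjusted p = 7.79e-09), Mir6913 inside Dohh (1.52) and the kinase Plk2 (1.5). The stress transcription factor Atf3 (1.40), the cysteine-synthesis enzyme Cth (1.37), Timp1 (1.33) and the inhibitory receptor Btla (1.25) rose too. The other large decreases were Ms4a4b, from 94.1 ± 32.5 to 31.1 ± 21.7 (-1.70, adjusted p = 0.0013), Mir7062 inside Adam8 (-1.32), BE692007, which lies beside Ms4a4b on chromosome 19 (-1.29), and Mir7006 inside Zfp512b (-1.23). They were followed by Cd7 (-1.21), Nsg2 (-1.18), LOC102639434 (-1.16), Tmem71 (-1.13), Ms4a6b (-1.10), Wscd2 (-1.09) and the interferon-inducible GTPase Iigp1 (-1.08).

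Of 25 ribosome biogenesis genes 22 rose (22 adjusted over the list alone), with Nolc1 (0.55), Gnl3 (0.53) and Wdr43 (0.43). Of 21 amino acid genes 17 rose (21 adjusted over the list alone), with the transcription factor Atf4 (0.47), Mthfd2 (0.50) and Slc7a5 (0.55). Cytokine genes rose in 11 of 19 cases (11 adjusted over the list alone), with Lif (1.07), Il5 (1.19) and Lta (1.08). NF-kB genes rose in 12 of 23 with 1 lower (13 and 1 adjusted over the list alone), with Nfkb2 (1.00), Birc3 (0.45) and Tnfaip3 (0.59). T cell activation genes had 11 of 20 higher and 3 lower (12 and 4 adjusted over the list alone), Nfatc1 (-0.39) among the lower. Camera adjusted p-values were 3.86e-12, 2.94e-12, 0.000158, 0.00102 and 0.000823, and each had adjusted p = 0.328 with an estimated correlation. The p53 list (10 of 15 higher and 2 lower, the same numbers adjusted over the list alone; 0.00134, adjusted p = 0.579 with an estimated correlation) included Cdkn1a (0.78), Sesn2 (0.63) and Mdm2 (0.27). Cholesterol synthesis (9 of 21, 12 adjusted over the list alone; 0.000805, adjusted p = 0.591 with an estimated correlation) included Lss (0.27), and glycolysis (4 of 19, 4 adjusted over the list alone; 0.0133, adjusted p = 0.645 with an estimated correlation) included Hk2 (0.57) and Slc2a1 (0.18). With fry, adjusted p was 0.000693 for ribosome biogenesis and for NF-kB genes, 0.000149 for amino acid genes and 3.23e-05 for cytokines. It was 0.000308 for T cell activation genes, 0.0044 for the p53 list, 0.0175 for cholesterol synthesis and 0.0375 for glycolysis.

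Naive and quiescence genes fell at high beads in 12 of 21 cases (13 adjusted over the list alone), with S1pr1 (-0.91), Dgka (-0.62) and Foxp1 (-0.54) beside Klf2. CD4 T cell identity genes fell in 8 of 16 (9 adjusted over the list alone), with the CD3 chains Cd3g (-0.47), Cd3d (-0.40) and Cd3e (-0.35). The camera adjusted p-values of 9.46e-06 and 0.000158 became adjusted p = 0.328 for both with an estimated correlation. Th1 genes had 5 of 16 lower and 1 higher (the same numbers adjusted over the list alone; 0.0204, adjusted p = 0.579 with an estimated correlation), with Stat4 (-0.70), Tbx21 (-0.41) and Cxcr3 (-0.83) lower. Platelet markers had 2 of 8 lower (2 adjusted over the list alone; 0.0379, adjusted p = 0.579 with an estimated correlation), namely Pf4 (-0.79) and the integrin Itgb3 (-0.81). With fry, adjusted p was 0.000693 for naive and quiescence genes and 0.00139 for CD4 T cell identity. It was 0.0175 for Th1 genes and 0.0241 for platelet markers.

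Further lists were not called with camera at high beads, several of them with members in both directions. Of these, Th2 genes (0.0416), Th17 genes (0.0175) and the IL-2 and STAT5 list (0.0175) had a fry adjusted p under 0.05. Th2 genes had 4 of 14 higher and 1 lower (0.214), with Il13 (1.22) and Il4 (0.72) higher, and Th17 genes 3 of 9 higher (0.0729), with Il21 (1.78) and Il1r1 (0.36). Tfh genes had 3 of 15 higher and 5 lower (0.516; median -0.04, mean 0.07), with Cd200 (1.12) higher and Bcl6 (-0.63) lower. Checkpoint receptors had 4 of 10 higher and 5 lower (0.694), with Pdcd1lg2 (0.61) higher and Entpd1 (-0.77) lower. Treg genes had 2 of 17 higher and 3 lower (0.215), with Ctla4 (-0.42). The interferon list had 3 of 22 higher and 8 lower (0.115), with Zbp1 (-0.76) and Isg20 (-0.86). The cytotoxic list had 1 of 12 higher and 2 lower (0.516), with Gzmb (-0.45). The TNF receptor list had 5 of 21 higher and 6 lower (0.644; median 0.01, test direction down), with Lta (1.08) higher and Cd27 (-0.47) lower. Survival BCL2 genes had Bcl2l1 (0.39) higher and Bcl2a1b (-0.46) lower of 6 (0.806). Pro-apoptotic genes had Bax (0.30) higher and Bcl2l11 (-0.52) and Bak1 (-0.20) lower of 8 (0.853; median 0.04, test direction down). The IL-2 and STAT5 list had 6 of 17 higher and 2 lower (0.144), with Myc (0.41) and Ccnd2 (0.25). DNA replication (0 of 27 higher, 1 lower, 0.655), mitosis (0 of 25 called, 0.386) and oxidative phosphorylation (2 of 24 higher, 0.222) were not called. Among marker lists, B cell (0 of 12, 0.771), NK cell (0 of 8, 0.386) and neutrophil genes (0 of 8, 0.738) had no called member. Plasma cell (1 of 8 lower, 0.771) and myeloid genes (1 of 15 lower, 0.215) had 1 each, and dendritic cell genes had 1 of 8 higher and 1 lower (0.771).

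In total 3397 genes were called at high beads, 1877 higher and 1520 lower, and 91 of 105 named called genes stayed called whichever library was left out. The number of calls was 2065 without anti-Ox40 high-bead replicate 1. The nuclear RNA score separated the antibody groups at high beads, at 5.99 to 6.17 with anti-Ox40 and 6.36 to 6.62 in control Ig. Of its 3 genes, Neat1 fell from 83.3 ± 11.2 to 56.2 ± 8.50 (-0.56, adjusted p = 0.00953), while Malat1 (-0.35, adjusted p = 0.434) and Xist (-0.17, adjusted p = 0.5) were not called. With the nuclear RNA score as a covariate, 3027 genes were changed by anti-Ox40 at high beads, 2534 of them among the 3397.

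**Figure D3:**
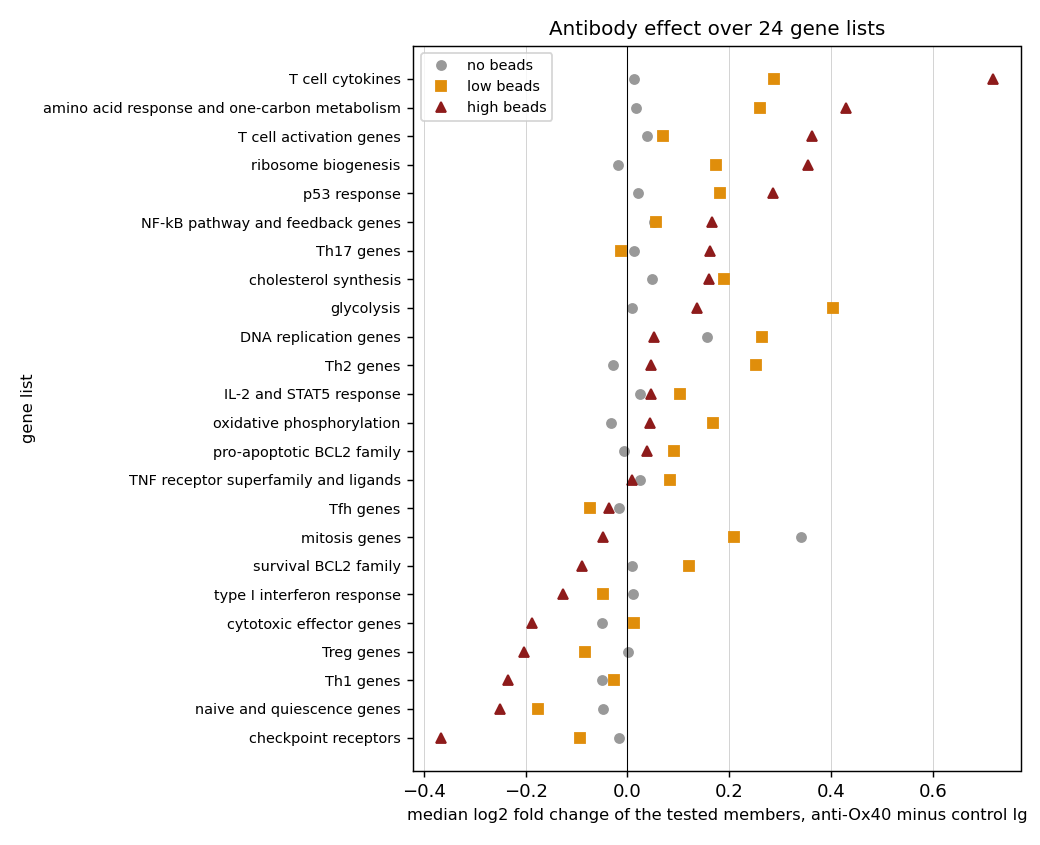
Median log2 fold change of the tested members (horizontal axis, anti-Ox40 minus control Ig) of each of the 24 theme lists (vertical axis), with a grey circle for no beads, an orange square for low beads and a dark red triangle for high beads. The T cell cytokine list reaches 0.72 at high beads, the glycolysis list 0.40 at low beads and the mitosis list 0.34 without beads.

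The next comparisons ask whether the antibody effect itself differed between bead doses. Between low and no beads the antibody effect on Slc16a3 differed (difference of log2 fold changes 1.01, SE 0.08, adjusted p = 3.89e-05). Mgarp (1.21), Egln3 (1.19), Batf3 (1.28) and LOC102642803 (0.94) were also among 34 genes with a higher and 1 with a lower effect. The lower one was Mir3112 inside Cstf2 (-0.96). Of 10 named genes called, 8 stayed called whichever library was left out, and Mir3112 did not. The glycolysis list had 9 of 19 members called (14 adjusted over the list alone; camera 1.57e-17, adjusted p = 0.104 with an estimated correlation), with Tpi1, Hk2 and Pfkl among them. None of Tnfrsf4 (0.12, adjusted p = 0.561), Tnfsf4 (0.15, adjusted p = 0.636), Il2ra (0.15, adjusted p = 0.481) and Cd69 (0.26, adjusted p = 0.282) was called. The count of 35 was 1866 without control Ig low-bead replicate 2, 67 without anti-Ox40 replicate 3 (no beads) and 19 to 23 without any of 6 others, namely control Ig replicates 1 and 2 and anti-Ox40 replicates 1 and 2 without beads, and control Ig replicate 3 and anti-Ox40 replicate 2 at low beads. It was 1 without the 6 libraries with the highest B cell markers, 17 with a fit to only the groups compared or with a nuclear RNA score as a covariate, 18 with a lung transcript score and 54 with quantile normalization.

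Between high and no beads the antibody effect differed for 1451 genes, 837 with a higher and 614 with a lower difference. Batf3 (2.16, SE 0.20, adjusted p = 8.76e-05), Il9 (2.07), Il21 (1.74), Bcl2l14 (1.68), Mir7041 (1.86) and Cd69 (0.78, adjusted p = 0.00296) were higher. Ms4a4b (-1.61), BE692007 (-1.46), Snord73a (-1.27), LOC102639434 (-1.24) and LOC102634375 (-1.21) were lower. Of 73 named genes called, 39 stayed called whichever library was left out. Il9, Mir7041, Ms4a4b, Snord73a, LOC102639434 and LOC102634375 did not. Ribosome biogenesis (15 of 25 higher, 19 adjusted over the list alone) and amino acid genes (12 of 21 higher, 16 adjusted over the list alone) had a larger effect at high beads, and mitosis genes (14 of 25 lower, 20 adjusted over the list alone) a lower one. The camera adjusted p-values were 6e-11, 3.17e-10 and 6e-11, each with adjusted p = 0.577 with an estimated correlation. Tnfrsf4 (0.02, adjusted p = 0.921), Tnfsf4 (0.36, adjusted p = 0.161) and Il2ra (0.25, adjusted p = 0.139) were not called. The count was 602 without anti-Ox40 high-bead replicate 1, 630 and 732 without control Ig high-bead replicates 3 and 2, and 957, 939 and 879 without control Ig replicates 1, 2 and 3 (no beads). It was 966 with no filter, 686 with a nuclear RNA score as a covariate, 7 without the 6 libraries with the highest B cell markers and 278 without the 6 with the lowest.

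Between high and low beads the antibody effect differed for 414 genes, 192 higher and 222 lower. Bcl2l14 (1.43, SE 0.11, adjusted p = 1.23e-05), Enpp2 (1.26), Btla (1.26), Timp1 (1.18), Plk2 (1.14) and Cd69 (0.52, adjusted p = 0.0356) had the larger effect at high beads. Mgarp (-1.11), Nsg2 (-1.04), the aldolase gene Aldoc (-1.02), Slc16a3 (-0.97) and the phosphatase gene Dusp6 (-0.97) had a negative difference. Mgarp rose less at high beads (0.06) than at low beads (1.18), as did Slc16a3 (0.14 and 1.11), and Aldoc went from 0.83 to -0.18. Nsg2 (-1.18 at high and -0.15 at low beads) and Dusp6 (-0.89 and 0.08) instead fell more at high beads. Of 38 named genes called, 11 stayed called whichever library was left out. Cd69, Enpp2, Timp1, Nsg2 and Dusp6 did not. In the glycolysis list 8 of 19 were lower (12 adjusted over the list alone; camera 4.45e-10, adjusted p = 0.538 with an estimated correlation). Tnfrsf4 (-0.10, adjusted p = 0.64), Tnfsf4 (0.20, adjusted p = 0.502) and Il2ra (0.10, adjusted p = 0.619) were not called. The count was 1243 without control Ig low-bead replicate 2, 653 without control Ig high-bead replicate 1 and 102 to 219 without any of 7 others, namely control Ig replicates 1 and 3 and anti-Ox40 replicates 1 and 3 at low beads, and control Ig replicates 2 and 3 and anti-Ox40 replicate 1 at high beads. It was 904 with a nuclear RNA score and 8 with a lung transcript score as a covariate, 263 with no filter, 152 with a fit to only the groups compared, and 3 and 102 without the 6 libraries with the highest or the lowest B cell markers. With the replicate number as a block it was 692. The lung score parted the antibody groups at low beads, so the count of 8 does not separate lung RNA from the antibody effect.

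The antibody effects at low and high beads overlapped. Of the genes higher at low beads 400 were also higher at high beads, against 115.4 if the calls were independent (Fisher's exact test, 2-sided, p = 9.46e-137). Likewise 206 of the genes lower at low beads were also lower at high beads, against 52.3 (p = 5.38e-77, exact). Only 6 and 10 called genes had opposite directions. Of the 18 genes higher without beads 8 were higher at low beads, against 1.1 (exact p = 4.97e-06), and 1 at high beads, against 2.6 (exact p = 0.499). These tests take genes as independent, and the compared effects share each gene's variance estimate from the single fit. Their p-values therefore do not measure agreement between cultures. Across the 13075 genes, which are not independent replicates, fold changes at low and high beads correlated with Pearson's r of 0.424 and Spearman's rho of 0.465. The antibody effect at low beads correlated with the change from no to high beads in control Ig (0.621 and 0.704), and 97.1% of the 1254 genes called had the same sign in both. For the antibody effect at high beads and the change from no to low beads these were 0.11 and 0.175, and 63.1% of 3397. The bead change differs between these 2 comparisons, so their values are not a measure of how the antibody effects differ.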

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

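The tests of nuclear RNA, of differences of single libraries, of lung RNA carried into libraries, of induction of lung transcripts by the antibody, and of B cells as the origin of calls at high beads were chosen only after the results they concern were seen.

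The following genes and lists stood out because their response to anti-Ox40 differed between bead doses, by a test of the difference itself in limma. Some of the genes lost their call when a single library was left out. These were Mir3112 (low against no), and Il9, Mir7041, Ms4a4b, Snord73a, LOC102639434 and LOC102634375 (high against no). For high against low beads they were Cd69, Enpp2, Timp1, Nsg2 and Dusp6. From no to low beads the antibody effect rose by 1.28 for Batf3, 1.21 for Mgarp, 1.19 for Egln3, 1.01 for Slc16a3 and 0.94 for LOC102642803 on the log2 scale, and the difference was -0.96 for Mir3112. The median difference was 0.26 for T cell cytokines (camera adjusted p = 0.000238, adjusted p = 0.234 with an estimated correlation) and 0.38 for glycolysis (1.57e-17, adjusted p = 0.104 with an estimated correlation).

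Between high and no beads the difference was 0.78 for Cd69, 2.16 for Batf3, 2.07 for Il9, 1.86 for Mir7041, 1.74 for Il21 and 1.68 for Bcl2l14. It was -1.61 for Ms4a4b, -1.46 for BE692007, -1.27 for Snord73a, -1.24 for LOC102639434 and -1.21 for LOC102634375. Median differences were 0.28 for T cell activation genes, -0.23 for naive and quiescence genes, 0.78 for T cell cytokines, -0.47 for mitosis genes, 0.39 for amino acid genes and 0.39 for ribosome biogenesis genes, and none of these 6 list calls held with an estimated correlation (adjusted p = 0.573 to 0.592).

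Between high and low beads the difference was 0.52 for Cd69, 1.43 for Bcl2l14, 1.26 for Enpp2, 1.26 for Btla, 1.18 for Timp1 and 1.14 for Plk2. It was -1.11 for Mgarp, -1.04 for Nsg2, -1.02 for Aldoc, -0.97 for Slc16a3 and -0.97 for Dusp6, and the median of the glycolysis list was -0.31 (4.45e-10, adjusted p = 0.538 with an estimated correlation). Antibody labels were exchanged within bead doses in 100 of the possible splits. For low against no beads 11 of the 100 splits gave at least the real 35 genes (highest other 543), for high against no beads 8 gave at least 1451 (highest other 1835), and for high against low beads 11 gave at least 414 (highest other 4146). Most antibody labels were kept at 1 dose and exchanged at the other in 53, 48 and 51 of the 100 splits, among them 6, 5 and 7 of those as large. Such a split adds antibody effects that the real one subtracts, so it is no reference without an effect. This does not account for the remaining splits as large, which include the real one. The median of the other splits was 0 genes in each comparison. The test therefore neither excludes chance nor shows it.

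The number of genes called at low beads rested on control Ig replicate 2, with 3522 calls without it and 1254 with it. That it was an anti-Ox40 culture like the other 3, with a wrong label, is argued against by 27 genes called between it and these (13 to 19 with any 2 of them), all 27 towards control Ig, where each of the other 17 libraries had at most 2 against the rest of its own group. It also had 741 against control replicates 1 and 3, and over the 3522 genes its median place between these (0) and anti-Ox40 (1) was 0.79 (0.93, 1.10 and 0.98 for the anti-Ox40 libraries), so an anti-Ox40 culture that responded less and a control culture that responded more cannot be told apart. Its departure from replicates 1 and 3 correlated across genes with the change from no to high beads at r = 0.386, above the 0.194 of the highest of the other 17 libraries, which is consistent with a culture further along in its response to beads. With a nuclear RNA score as a covariate 215 of the 1254 genes stayed called and the median fold change in their direction went from 0.26 (median SE 0.06) to 0.20 (0.06), with all 1254 signs kept, but at low beads the score itself parts control replicates 1 and 3 (7.88 and 7.80) from replicate 2 (6.93) and anti-Ox40 (7.14 to 7.21), so nuclear RNA yield and the antibody effect cannot be told apart.

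Transcripts of lung airway and alveolar cells appeared in cultures of spleen T cells. The antibody as the only source is argued against by Scgb1a1 above 0 in 5 of 9 control Ig libraries. This does not exclude a rise added by the antibody at low beads. Induction that grows with bead dose was not settled by a difference in lung score between high and low beads of 0.02 (6 libraries each, exact permutation p = 0.957, 2-sided). Lung RNA carried into some libraries may be a source, since 11 of 16 lung genes that reached an nRPKM of 1 followed Scgb1a1 and 15 of 18 were highest in anti-Ox40 low-bead replicate 3, where Scgb1a1 was at 148 and Sftpc at 45.3. Both counts include Scgb1a1 itself, whose place was fixed by the choice of reference. The other 5 were above 0.1 in a library without Scgb1a1, among them Napsa (up to 4.66) and Chil1 (up to 6.01). At low beads Scgb1a1 was at 0, 16.4 and 18.2 in control Ig and at 41.4, 26.5 and 148 with anti-Ox40. Sftpc moved with it, at 0, 4.42 and 4.61 and at 13.8, 7.9 and 45.3. At high beads Scgb1a1 ran from 19.5 to 84.3. These differences within a dose argue against levels set by bead dose alone. All libraries without beads lacked Scgb1a1. Carried-over RNA, a bead effect that varied between libraries and an added antibody effect at low beads therefore cannot be told apart.

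B cell markers were high in 1 library of each group, replicate 3 in all 6, in cells enriched with a kit meant to remove B cells. Over 12 B cell genes outside the marker list, 86.1% of 72 pairs of gene and group were highest in that library (33.3% by chance), which is consistent with B cells carried into these libraries, with Ms4a1 at 11.9 at most. As the whole origin of the calls at high beads this is argued against, since 3273 of 3397 genes stayed called with the B cell score as a covariate. Leaving out the 6 libraries lowered the calls to 1387, and leaving out the 6 with the lowest scores lowered them to 2100. No biological explanation was tested, since the labels name no difference between replicates.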

How the results depend on the processing

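The alternatives that leave out libraries by their B cell markers, add a covariate or add a replicate block were chosen after seeing the data. By the labels, replicate numbers are only the order of the libraries. In its deviation from the group mean, each of the 18 libraries correlated best with 1 of its own number in another group. All 18 also had their highest mean correlation with libraries of their own number. The numbers therefore track something shared between groups that the labels do not name, and the main fit takes no account of it. Correlations were over 0.1 for 31 of 45 pairs with the same number (mean 0.142) and 2 of 90 with different numbers (-0.0711). With the number as a replicate block, 18 calls became 59 (anti-Ox40, no beads) and 414 became 692 (difference, high against low beads), and no other count moved by over 1.5 times. The block kept all 30 list calls and 705 of 709 named results, adding Tnfrsf4 with anti-Ox40 at low beads (adjusted p = 0.022) and ending Mir7029 there, Mir3112 for low against no beads and Atp5b for high against no beads. The splits of libraries took no account of these numbers. The bead comparisons within control Ig kept their counts within 1.5 times under all alternatives run except high against low beads with the nuclear RNA covariate (5728). With any 1 library left out they ranged from 7494 to 7837, 10473 to 10541 and 8857 to 9511. With any 1 left out the antibody counts ranged from 0 to 30 (no beads), 131 to 3522 (low) and 2065 to 3363 (high), and the differences between doses from 19 to 1866 (low against no), 602 to 1743 (high against no) and 102 to 1243 (high against low). Lists called ranged from 4 to 8, 12 to 14 and 9 to 14, and the correlations from 0.365 to 0.438 (low with high beads), 0.529 to 0.63 (antibody at low beads with beads high against no) and 0.088 to 0.131 (antibody at high beads with beads low against no). Among 709 named results, median-ratio rescaling ended 1 call, quantile normalization 22, and removal of the 6 B-marker-high libraries 222, with 6 instead of 12 residual degrees of freedom. The filter at 5 could give no value for the named genes under it.

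Without beads, the 18 calls became 86 and 32 with pseudocounts of 0.1 and 0.5, 9 with no filter (more genes tested), 3 with only the groups compared (4 residual degrees of freedom), 10 with no trend, 0 and 2 without the 6 libraries with the highest and the lowest B cell markers, and 42 with the nuclear covariate. At low beads, 1254 became 557 with no filter, 45 with only the groups compared, 24 and 1923 without the libraries highest and lowest in B cell markers, 222 with the nuclear and 123 with the lung covariate. The highest set held control Ig low-bead replicate 3 and the lowest set replicate 2, and the lung score parted the antibody groups at low beads. At high beads, 3397 became 1387 and 2100 without those sets. For low against no beads, 35 became 54 with quantile normalization, 17 with only the groups compared, 1 without the B-marker-high libraries, 17 with the nuclear and 18 with the lung covariate. For high against no beads, 1451 became 966 with no filter, 7 and 278 without the B-marker-high and B-marker-low libraries, and 686 with the nuclear covariate. For high against low beads, 414 became 263 with no filter, 152 with only the groups compared, 3 and 102 without those sets, 904 with the nuclear and 8 with the lung covariate. Lists called without beads (5) became 8 with only the groups compared, 9 with the nuclear covariate and 0 with an estimated correlation, which also gave 0 at low (13) and high beads (12).

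The correlation of low with high beads (0.424) became 0.34 and 0.399 with pseudocounts of 0.1 and 0.5, 0.378 with no filter, 0.498 with the filter at 5, 0.331 without the B-marker-low libraries and 0.368 with the nuclear covariate. The antibody effect at low beads with beads high against no (0.621) became 0.521 with a pseudocount of 0.1, 0.58 with no filter, 0.696 with the filter at 5, 0.574 and 0.573 without the B-marker-high and B-marker-low libraries, and 0.53 with the nuclear covariate. The antibody effect at high beads with beads low against no (0.11) became 0.128 with the filter at 5, 0.078 with quantile normalization, 0.066 without the B-marker-low libraries and 0.005 with the nuclear covariate. Reversed signs occurred for Cyp2f2 at low beads with the lung covariate (-0.008), for Il2ra high against low beads with it (-0.005), and for Tnfrsf4 high against no beads, whose main difference was 0.02, with quantile normalization (-0.009), the lung covariate (-0.009), without the B-marker-low libraries (-0.044) and in 4 fits with 1 library left out (-0.018, -0.001, -0.046 and -0.011). Apart from the fits noted as having more genes or fewer libraries, the cause was not tested. With 26.4 to 46.0 reads behind an nRPKM of 1 over 1 kb, depth limits genes under that level most, and p-values measure only the spread between these libraries.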

Other observations

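The sign test against the bead response was chosen only after the result was seen, and the test of further hypoxia-inducible factor targets was set before its result was seen.

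Glycolysis genes, Egln3 and Mgarp are known targets of hypoxia-inducible factor or lie near that response, and further targets outside the named genes were higher with anti-Ox40 at low beads. Plod2 rose from 3.42 ± 0.35 to 5.36 ± 0.21 (SD, n = 3; log2 0.53, limma adjusted p = 0.00433), Ddit4 from 45.3 ± 0.97 to 63.8 ± 3.97 (0.48), Sap30 by 0.45, Gbe1 by 0.43, Higd1a by 0.40, the carbonic anhydrase Car12 by 0.36, P4ha1 by 0.33 and Jmjd6 by 0.32. Of 25 such genes 11 rose and 0 fell, and 21 had a positive value. Their median of 0.12 lay at percentile 99.93 of 10000 random lists matched on expression (95% of these between -0.07 and 0.08), which may reflect a wider response of such targets, although these genes vary together and random lists do not. The random lists were not matched on the response to beads. The test therefore cannot separate a response of these targets from a general shift in the direction of more beads. The median was -0.04 without beads (0 called) and 0.12 at high beads (7 higher and 3 lower, with Pdk1 at -0.32 and Ccng2 at -0.34).

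Of the 1254 genes called at low beads, 97.1% had the sign of the change from no to high beads in control Ig, which may mean that anti-Ox40 at low beads acted in the direction of more beads. At high beads 63.1% of 3397 called genes had the sign of the change from no to low beads. That other bead change was used because it shares no library with this antibody effect, so the 2 shares cannot be set against each other. Stra6, Il21, Il9, Batf3 and Slc16a3 rose with beads in control Ig and with anti-Ox40 at low beads. The test does not separate this from cultures that differed in their stimulation by chance, given the place of control Ig low-bead replicate 2.

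The 6 libraries of each pair of groups can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split was 1 of 10 with the most calls in all 6 comparisons of 2 groups. Its calls and the highest of the other splits were 18 and 0 for anti-Ox40 without beads, 1254 and 5 at low beads, 3397 and 3 at high beads, 8152 and 0 for low against no beads, 10767 and 0 for high against no beads and 9483 and 0 for high against low beads. For lists called by camera at the preset correlation, 7 of 10 splits gave at least the real 5 without beads (highest other 12), 3 gave at least 13 at low beads (18) and 4 gave at least 12 at high beads (13). The median of the other splits was 9 lists without beads, 11 at low and 10 at high beads. The number of lists called at the preset correlation therefore does not set the real split apart from mixed ones.

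Gapdh was listed at 1.16 to 9.48 per library, far below Tpi1 (16.1 ± 1.09 without beads and 660 ± 6.04 with high beads in control Ig), and LOC102642803 followed Tpi1 at 29.1 ± 1.85 and 1170 ± 8.25 in the same groups. Reads shared with copies of these genes elsewhere could not be examined from this table. Xist was at 84 in control Ig low-bead replicate 2 against 148 and 143 in replicates 1 and 3, and Neat1 at 121 against 192 and 177. Hbb-b1 was at 0.33 ± 0.08 in control Ig and 1.33 ± 0.86 in anti-Ox40 at low beads, and the erythroid list's single tested gene Tfrc, the transferrin receptor of dividing cells, was higher with anti-Ox40 by 0.28 at low and 0.37 at high beads. The CD8 list had a single tested gene as well.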
